A study of Mus musculus with 8 samples.

How the data were processed

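Total RNA of mSCC-20 cells, a mouse cutaneous squamous cell carcinoma line, was labelled with Cy3 and hybridised to 8 single-colour Agilent mouse expression arrays. Per the labels, 4 arrays carried RNA of cells transfected with a control microRNA (NC), 2 of cells given miR-193b-3p and 2 of cells given miR-365a-3p. The labels also give an amount in µg, 0.2 for NC replicates 1 and 2 and both miR-193b replicates, and 0.6 for NC replicates 3 and 4 and both miR-365a replicates. These are called the 0.2 set and the 0.6 set. Slide numbers put NC replicate 1 and miR-193b replicate 1 on slide 1, NC replicate 2 on slide 2, miR-193b replicate 2 on slide 3 and the whole 0.6 set on slide 4.

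Spot values are intensity in arbitrary units, per the file headers the processed signal of Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within each array and not normalized between arrays. A deposited table of log2 values for the same 8 arrays was also used. In the deposited table the sorted log2 values of all arrays were nearly equal, as after quantile normalization, with medians of 7.04 to 7.05. Each of its columns correlated best with the scanner values of its own array (r across spots of 0.965 to 0.981). Limma is named in the submitters' processing notes; the background correction behind the deposited log2 values is not stated there.

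Control spots and spots with a non-uniformity or population outlier flag were left out. The log2 processed signal was centred on each array's 75th percentile of gene spots, and spots of a probe were averaged. Of 39429 probes, 27508 were named through a current accession table, 3544 through a current symbol and 404 through a synonym, and 7973 kept the name in the files. This gave 30139 names, each represented by its brightest probe over all 8 arrays. A gene was tested if its probe was well above background on both arrays of at least 1 of the 4 combinations of transfection and set, which held for 17855 genes. Probe positions are those of the files, on mm9, with the start above the end for probes on the minus strand.

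Effects were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 8 arrays, with terms for the set, miR-193b and miR-365a. The set term compares each microRNA with the 2 NC arrays of its own set, so the comparisons share no NC array. The fit left 4 residual degrees of freedom, and the prior added 2.31. P values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are standard errors of this fit. The difference between the effects of the microRNAs, and between the NC arrays of the sets, were tested as contrasts of the same fit. Slide 1 and slides 2 and 3 also gave the miR-193b difference separately.

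Before the data were examined, 31 gene lists were fixed, and the 30 with at least 5 measured genes were tested with camera (preset correlation of 0.01), adjusted over the lists within each comparison. The melanocyte list, with 4 measured genes, was not tested. Camera with an estimated correlation and fry were run beside it. Called members were also counted with p adjusted over the list alone. The rule for named genes was fixed at the same time. It took reported targets, Max and Ccnd1 among them, then the 8 largest rises and 8 largest falls among called genes with symbols whose treated and NC arrays did not overlap. For each list with a camera call or at least 3 called members it added up to 4 members with the smallest p. Because dim probes led the ranking, the 10 largest rises and falls among genes well above background on all 4 arrays of the set were added after the values were seen. For a gene well above background on 1 side only, the text gives a lower bound. It sets the array of that side with the lower level against the mean of the other side. In that mean each array counts at the lowest level of any probe well above background on it, or at the gene's own level if higher. Where the own level is the higher, the bound is only the measured ratio. Some genes that the rule selects are not reported here.

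The fitting steps were tested on simulated data of 17784 genes with 200 singly changed genes per comparison. A further list of 44 genes for miR-193b and of 90 for miR-365a was shifted down. These lists are left out of the rates and false calls below. For miR-193b the calls held 0 of 67 genes changed 1.41-fold, 28.4% of those changed 2-fold and 87.9% of those changed 4-fold, with 1 false call. For miR-365a the counts were 0 of 67, 20.9% and 78.8%, with 3 false calls. In this simulation, with 2 arrays per group, genes with small changes were mostly not called. Its rates need not hold for the data, because its errors were independent between arrays and fewer genes changed than were called after miR-365a. Of 2814 genes called there, 396 rose and 681 fell by at least 2-fold, so most calls were of smaller changes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the values and drew the plots, and statmod 1.5.0 served the random block.

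Alternatives were normexp background correction (offset of 50), quantile normalization, the deposited log2 values, other filters on dim probes, slide as a random or fixed term, no set term, the own set alone, a trended robust variance, other ways from probe to gene, other thresholds, and leaving out each array in turn. Seed sites in 3′ untranslated regions were planned but not analysed here. The probe sequences were searched instead.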

Results

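Messenger RNA levels were compared between mSCC-20 cells transfected with a control microRNA (NC, 4 arrays), miR-193b-3p (2 arrays) or miR-365a-3p (2 arrays). The line comes from a cutaneous squamous cell carcinoma of an FVB/N mouse, and both microRNAs are processed from transcripts of the same genomic cluster. Each array had 43020 gene spots. Of these, 51.4% to 54.6% were well above background in the 0.2 set and 58.9% to 62.1% in the 0.6 set, with 0 saturated spots. The median local background was 55 to 60.5 in the 0.2 set and 26 to 30 in the 0.6 set. The labels give an RNA integrity number of 10 for every sample. With 2 arrays per group and set, the number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p values measure only the spread between these arrays.

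The first comparison asked which transcripts changed when the carcinoma cells received miR-193b. Stmn1, encoding the microtubule-destabilising protein stathmin, fell 2.84-fold against the NC arrays of the same set (log2 difference -1.51 ± 0.11, SE, n = 2 and 2, adjusted p = 0.0109), and both of its probes were called. Ywhaz, a 14-3-3 adaptor gene, fell 2.01-fold (SE 0.15 on the log2 scale, adjusted p = 0.0332). Max, the dimerisation partner of MYC, had a log2 difference of -0.62 ± 0.13 (adjusted p = 0.0638), and Ccnd1, encoding the G1 cyclin D1, one of -0.57 ± 0.21 (adjusted p = 0.194); neither was called. The probes lie on mm9 at chromosome 12, 78038331 to 78038272 (Max), and chromosome 7, 152116261 to 152116202 (Ccnd1). Of 3 Ywhaz probes, from -1.25 to -0.71, only 1 was called.

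Of 15 measured genes reported earlier as targets of miR-193b, 3 fell, 0 rose and 12 were not called (6 fell adjusted over the list alone). The list median was -0.57 (camera adjusted p = 1.66e-05). With an estimated correlation the adjusted p was 0.520. Members of it, Max among them, were proposed as targets from work on these cells, so the list is not independent evidence of its direction. Of 12 reported targets of miR-365, 2 fell, the phosphatase gene Cdc25a (-0.87 ± 0.15) among them, and 10 were not called (3 fell adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.0170), and the adjusted p was 0.520 with an estimated correlation. This list also holds Max and is not independent evidence either. Its call was lost without NC replicate 2 (adjusted p = 0.0596) and without miR-193b replicate 2 (adjusted p = 0.0947), in the range of 0.00130 to 0.520 over all alternatives of the reported targets of miR-365 list after miR-193b.

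Genes of the cell cycle were lower after miR-193b. The mitosis list had a median log2 difference of -0.56 with all 44 measured members below 0 (camera adjusted p = 9.75e-20), and the adjusted p was 0.729 with an estimated correlation. Of the 44, 4 fell, 0 rose and 40 were not called, and 30 fell adjusted over the list alone. The 4 were Ccna2, encoding cyclin A2 (-1.02 ± 0.18), the kinesin gene Kif23 (-0.92 ± 0.14), the spindle midzone gene Prc1 (-0.76 ± 0.12) and the spindle checkpoint kinase gene Bub1b (-0.74 ± 0.12). The list of G1-S and DNA replication genes had a median of -0.49 (camera adjusted p = 2.33e-13), again with an adjusted p = 0.729 with an estimated correlation. In it 3 of 44 fell, 0 rose and 41 were not called (20 fell adjusted over the list alone). They were Dtl, a substrate receptor of a ubiquitin ligase (-1.16 ± 0.14), the replicative helicase factor gene Cdc45 (-1.08 ± 0.17), and Cdc25a. Within slide 1 alone the mitosis median was -0.56 (43 of 44 lower) and across slides 2 and 3 it was -0.53 (44 of 44 lower). The G1-S and replication median was -0.49 on slide 1 and -0.50 on slides 2 and 3.

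The p53 target list shifted upward, with a median of 0.28 (camera adjusted p = 0.0170), and the adjusted p was 0.729 with an estimated correlation. Of its 24 genes 3 rose, 0 fell and 21 were not called (5 rose adjusted over the list alone). Btg2, an antiproliferative gene, rose 2.99-fold (1.58 ± 0.23), the proapoptotic gene Bbc3 rose 2.24-fold (1.16 ± 0.21), and Ddit4l, not well above background in NC cells, rose at least 2.56-fold. Perp, a desmosomal p53 target, had a difference of 0.57 ± 0.13 (adjusted p = 0.0761). The list median was 0.25 within slide 1 and 0.26 across slides 2 and 3. The call of the p53 targets list after miR-193b was lost without NC replicate 2 (adjusted p = 0.190, in a range of 0.00191 to 0.729 over its alternatives). In the MYC-MAX network, 2 of 12 genes rose, Mxd4 (1.23 ± 0.21) and Mxd1 (0.93 ± 0.16), which encode MAX-binding repressors. Mxd3, of the same family, fell by 1.41 on the log2 scale (SE 0.21), with 1 of its 2 miR-193b arrays not well above background; 9 were not called (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.816).

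The other lists were not called after miR-193b (camera adjusted p from 0.0579 to 0.921) and had at most 2 called members each. Of all genes tested 2.9% were called in this comparison. In the RAS-MAPK pathway 1 of 19 genes fell and 18 were not called (2 fell adjusted over the list alone). Other falls were those of the ETS factor gene Etv5 among 19 MAPK-responsive genes (-0.96 ± 0.14), and the metalloproteinase inhibitor gene Timp2 among 23 invasion genes (-1.03 ± 0.14). Stmn1 and Rhoc, a small GTPase gene, fell among 30 genes of cytoskeleton and migration. Rises were those of Btg2 and Tob1 among 19 CDK inhibitor and quiescence genes, Bbc3 among 26 apoptosis genes, and Grhl1 and Ivl, a keratinocyte transcription factor and an envelope protein gene, among 25 epidermal differentiation genes. Krt16 rose among 9 keratins of hyperplasia and carcinoma, F11r among 25 epithelial junction genes, Tgfbi among 19 mesenchymal transition genes, Sel1l among 20 chaperone genes of the endoplasmic reticulum, and Esam among 6 endothelial markers. Adjusted over the list alone, 3 basal keratinocyte genes of 17 and 4 junction genes rose, 4 differentiation genes rose and 1 fell, 2 chaperone genes rose and 1 fell, 2 of 25 MYC-responsive ribosome biogenesis genes fell, and 1 apoptosis gene and 1 keratin fell beside the rises of Bbc3 and Krt16. In 12 lists limma called 0 members over all genes. They were those of ribosome biogenesis, basal keratinocyte, interferon response (32 genes), NF-kB and cytokine (26), cholesterol synthesis (23), integrated stress response (27), glycolysis and hypoxia (25), TGF-beta pathway (23), microRNA machinery (15), mitochondrial respiration (25), and fibroblast and leukocyte markers (6 each). These hold 249 distinct genes, of which 34 had an unadjusted p under 0.05. Median, mean and test differed in sign for the apoptosis, microRNA machinery and fibroblast lists.

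Among genes above background on all 4 arrays of the set, listed after their values were seen, the largest rise was that of Bnc2, a zinc finger gene (2.42 ± 0.16, 5.33-fold, adjusted p = 0.00947). It was followed by the histone gene H2bc4 (2.01 ± 0.33), the antimicrobial peptide gene Defb14 (1.94 ± 0.34), Vasn, Chit1, Krt16 (1.76 ± 0.19), Cd93, Stra6 and Fyco1 (1.73 ± 0.16). The largest falls were those of Apln, encoding the peptide apelin (-2.23 ± 0.28, 4.69-fold, adjusted p = 0.0245), F2rl1, a protease-activated receptor gene (-1.96 ± 0.29), the acetyltransferase gene Kat2b (-1.90 ± 0.19) and Rhoc (-1.75 ± 0.22). Then came the ceramidase gene Asah1, the receptor tyrosine kinase gene Axl (-1.69 ± 0.10, adjusted p = 0.00947), Hdgfl3, Plagl2, Lpcat1 and the centromere gene Mis18a. Second probes of Vasn (0.44), Asah1 (-1.10), Hdgfl3 (-0.50) and Plagl2 (-1.04) were not called. The rule fixed beforehand led to dim probes. Among rises, Olfr655 was at least 4.93-fold higher, Mdga2 at least 3.34-fold, Peg10 at least 2.95-fold, Fam43b at least 2.87-fold, Vmn2r97 at least 1.48-fold and Fam183b at least 1.24-fold, beside Ddit4l. None of these was well above background in NC cells, and each bound is that of the lower miR-193b array. Among falls, Ace3 was at least 1.80-fold lower, Olfr1161 at least 1.68-fold, Zfp37 at least 1.65-fold, Efcc1 at least 1.62-fold, and D11Ertd712e and L3mbtl4 at least 1.56-fold, by the lower NC array. None was well above background after miR-193b; Apln and F2rl1 completed them.

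In all, 519 of 17855 genes were called after miR-193b, 313 higher and 206 lower, of which 188 and 99 by at least 2-fold. At an unadjusted p under 0.05 there were 3806. Of the 519, 417 were well above background on at least 1 array of each side, 57 dim in NC, 23 dim after miR-193b and 22 on neither side. The arrays of the groups did not overlap for 52.0% of genes, where chance gives 33.3%. Within slide 1 the differences were -0.50 for Max, -0.66 for Ccnd1 and -1.44 for Stmn1, against -0.74, -0.47 and -1.57 across slides 2 and 3. The number of calls moved widely between fits. The genes called after miR-193b numbered 0 in limma with the 0.2 set fitted alone (3108 unadjusted), 11 without a filter on dim probes, and fewer without any 1 array, but 848 with the deposited log2 values, 871 with probes above background on all 8 arrays, 975 with normexp background correction, 1042 with a trended robust variance and 1368 with neighbouring arrays as a block (chosen after the data were seen). There were 136 without NC replicate 1, 281 without NC replicate 2, 103 without miR-193b replicate 1, 129 without miR-193b replicate 2, 29 without either miR-365a replicate and 167 without NC replicate 3 or 4. The call of Stmn1 after miR-193b was lost in the 0.2 set alone (adjusted p = 0.133, in a range of 0.00190 to 0.133 over its alternatives).

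**Figure D1:**
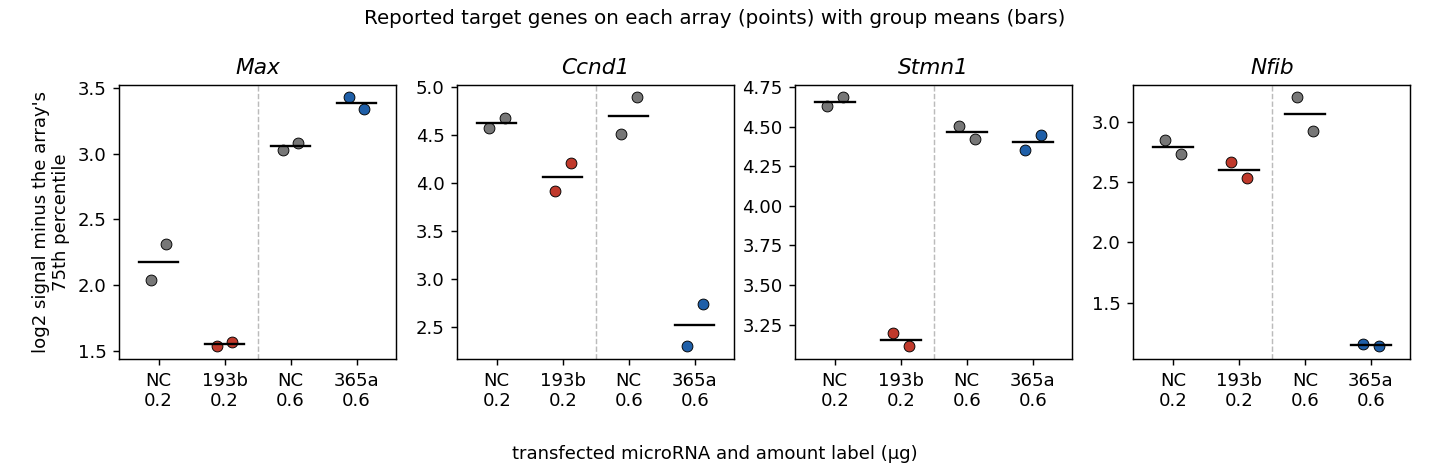
Normalised log2 signal (log2 minus the array's 75th percentile, vertical axis) of Max, Ccnd1, Stmn1 and Nfib on each array (points), with group means (bars), by microRNA and amount label in µg. Stmn1 lies lower after miR-193b (-1.51 on the log2 scale), and Ccnd1 (-2.19) and Nfib (-1.92) after miR-365a.

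The second comparison asked the same of miR-365a, within the 0.6 set. Ccnd1 fell 4.55-fold (log2 difference -2.19 ± 0.21, SE, n = 2 and 2, adjusted p = 0.00416), from a normalised log2 signal of 4.70 ± 0.27 on the NC arrays to 2.51 ± 0.31 (SD, n = 2 each). Max had a difference of 0.33 ± 0.13 and was not called (adjusted p = 0.147). Nfib, encoding the transcription factor NFIB, fell 3.78-fold (-1.92 ± 0.14, adjusted p = 0.00245), with all 5 of its probes called, and Arrb2, a beta-arrestin gene, fell 2.02-fold (-1.01 ± 0.11, adjusted p = 0.00509). Of 12 reported targets of miR-365, 6 fell, 0 rose and 6 were not called (7 fell adjusted over the list alone). Members that fell also included the histone deacetylase gene Hdac4 (-0.87 ± 0.15) and Hoxa9 (-0.77 ± 0.15). The median was -0.64 (camera adjusted p = 1.88e-04), and the adjusted p was 0.275 with an estimated correlation. As it holds Max, this list is again not independent evidence of its direction. Of 15 reported targets of miR-193b, 4 fell, among them Ccnd1, the TGF-beta mediator gene Smad3 (-1.41 ± 0.16) and Ets1 (-1.53 ± 0.37). Il17rd, an inhibitor of growth factor signalling, rose by 0.77 (SE 0.17), and 10 were not called (the same counts adjusted over the list alone; camera adjusted p = 0.245).

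Mitotic genes fell together after miR-365a. Of 44 measured, 39 fell, 0 rose and 5 were not called (44 fell adjusted over the list alone). The median was -0.997 (camera adjusted p = 2.48e-24), with an adjusted p = 0.549 with an estimated correlation. The centrosomal kinase gene Nek2 fell 3.38-fold (-1.76 ± 0.21), the cyclin F gene Ccnf 2.21-fold (-1.14 ± 0.12), Bub1b 2.15-fold (-1.10 ± 0.12) and the checkpoint kinase gene Ttk 2.09-fold (-1.06 ± 0.13). Among 44 genes of G1-S and DNA replication, 13 fell, 0 rose and 31 were not called (27 fell and 1 rose adjusted over the list alone). Their median was -0.60 (camera adjusted p = 2.44e-10), and the adjusted p was 0.627 with an estimated correlation. NC replicate 4 lay low for this list, and the median of the G1-S and DNA replication list after miR-365a was -0.37 without NC replicate 3 and -0.81 without NC replicate 4. The origin licensing genes Cdc6 (-1.95 ± 0.20, 3.85-fold) and Cdt1 (-1.14 ± 0.13), the helicase subunit gene Mcm5 (-1.66 ± 0.20) and Uhrf1, which maintains DNA methylation at replication (-1.39 ± 0.20), had the smallest p. The ribosome biogenesis list of MYC-responsive genes had 5 of 25 lower, 0 higher and 20 not called (5 adjusted over the list alone). Its median was -0.25 (camera adjusted p = 2.95e-04; adjusted p = 0.627 with an estimated correlation). Odc1, the ornithine decarboxylase of polyamine synthesis, fell 3.66-fold (-1.87 ± 0.19), and Rrs1 (-0.80 ± 0.11), Rcl1 (-0.80 ± 0.12) and the pyrimidine synthesis gene Cad (-0.71 ± 0.14) fell too.

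Genes that respond to MAP kinase signalling were lower. Of 19, 9 fell, 0 rose and 10 were not called (9 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 3.84e-05; adjusted p = 0.275 with an estimated correlation). Besides Ccnd1, the signalling inhibitor gene Spred1 (-1.10 ± 0.15) and the ETS factor genes Etv4 (-1.26 ± 0.21) and Etv5 (-0.77 ± 0.14) had the smallest p. In the RAS-MAPK pathway itself 2 of 19 fell, the kinase gene Braf (-1.09 ± 0.18) among them, with 17 not called (2 fell adjusted over the list alone; camera adjusted p = 0.826). In the MYC-MAX network 3 of 12 rose, Mxd4 (1.38 ± 0.21), Mxd1 (0.84 ± 0.16) and Mlx (0.51 ± 0.13), and 9 were not called (5 rose adjusted over the list alone; camera adjusted p = 0.159). Its member Mycl, not well above background in NC cells, was not called (adjusted p = 0.0507).

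The p53 target list moved upward by a median of 0.45 (camera adjusted p = 0.0332), and the adjusted p was 0.801 with an estimated correlation. In it 7 of 24 rose, 2 fell and 15 were not called (10 rose and 2 fell adjusted over the list alone). The proapoptotic genes Bbc3 (1.61 ± 0.21, 3.05-fold) and Pmaip1 (2.82-fold, SE 0.17 on the log2 scale), Trp53inp1 (1.48 ± 0.16) and the death receptor gene Tnfrsf10b (0.81 ± 0.14) rose. The call of the p53 targets list after miR-365a was lost without NC replicate 3 (adjusted p = 0.0807) and without miR-365a replicate 2 (adjusted p = 0.0597), in a range of 0.00147 to 0.801 over its alternatives. Among 26 apoptosis genes 7 rose and 5 fell (9 and 5 adjusted over the list alone), with rises of Bcl2l11 (0.80 ± 0.11) and Bmf (0.95 ± 0.14), both proapoptotic, beside Bbc3 and Pmaip1; the list was not called (camera adjusted p = 0.159). Of 19 CDK inhibitor and quiescence genes 3 rose, Cdkn2b (1.53 ± 0.20, 2.89-fold), Cdkn2a (0.84 ± 0.16) and Tob1 (0.58 ± 0.13). Klf4, a keratinocyte transcription factor gene, fell by 0.91 (SE 0.16), and 15 were not called (the same adjusted over the list alone; camera adjusted p = 0.143).

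Basal keratinocyte genes had a median of -0.36 (camera adjusted p = 0.0207; adjusted p = 0.690 with an estimated correlation). The hyaluronan receptor gene Cd44 (-1.71 ± 0.23) and the integrin gene Itga6 (-0.80 ± 0.14) fell and 15 of 17 were not called (2 fell adjusted over the list alone). Probes disagreed for these genes, down to -0.53 for Cd44 and at 0.17 for a second Itga6 probe. The call of the basal keratinocyte list after miR-365a was lost without NC replicate 4 (adjusted p = 0.0928) and without miR-365a replicate 1 (adjusted p = 0.0511), in a range of 0.00100 to 0.690 over its alternatives. The glycolysis and hypoxia list had a median of -0.19 (camera adjusted p = 0.0190; adjusted p = 0.627 with an estimated correlation), with 3 of 25 lower and 22 not called (3 adjusted over the list alone). Adm, encoding the vasoactive peptide adrenomedullin (-2.05 ± 0.29), the angiogenic factor gene Vegfa (-2.05 ± 0.37) and the glycolytic enzyme gene Aldoa (-0.46 ± 0.10) fell. The call of the glycolysis and hypoxia list after miR-365a was lost without NC replicate 3 (adjusted p = 0.0807) and without miR-365a replicate 2 (adjusted p = 0.0597), in a range of 0.00346 to 0.627. In cholesterol synthesis 6 of 23 fell, 0 rose and 17 were not called (6 adjusted over the list alone), among them Sc5d (-1.52 ± 0.13) and Sqle (-0.79 ± 0.16), enzymes of the pathway, its regulator Srebf2 (-1.49 ± 0.29) and the transporter gene Stard4 (-0.84 ± 0.12). The list median was -0.09 and its mean -0.34 (camera adjusted p = 0.0392; adjusted p = 0.823 with an estimated correlation). The call of the cholesterol synthesis list after miR-365a was lost without miR-365a replicate 1 (adjusted p = 0.0511), without miR-365a replicate 2 (adjusted p = 0.0597) and without NC replicate 3 (adjusted p = 0.0699), in a range of 0.0178 to 0.823.

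Lists not called by camera after miR-365a also held called genes. Of all genes tested 15.8% were called in this comparison. Several of these lists held about that share, so their counts alone show no response of the list. Among 23 invasion and matrix proteolysis genes 5 fell and 1 rose (6 and 2 adjusted over the list alone), with falls of Cd44, Adam10 (-0.58 ± 0.12) and Adam17 (-0.89 ± 0.18). Among 30 genes of cytoskeleton and migration 4 fell and 1 rose (5 and 1 adjusted over the list alone). There the tropomyosin gene Tpm4 (-1.58 ± 0.16), the focal adhesion kinase gene Ptk2 (-1.34 ± 0.14) and the profilin gene Pfn1 (-0.99 ± 0.17) fell and Arpc5 rose by 0.83 (SE 0.19), although second probes of Ptk2 (-0.31) and Pfn1 (0.02) were not called. Of 23 TGF-beta pathway genes 3 fell, Smad3 and the receptor gene Bmpr1a (-0.77 ± 0.14) among them, and Id3 rose by 0.94 (3 fell and 2 rose adjusted over the list alone). Of 26 NF-kB and cytokine genes, Vegfa, Csf3 (-1.42 ± 0.31) and Ptgs2 (-1.16 ± 0.28) fell and the chemokine gene Ccl7 rose by 2.55 (the same adjusted over the list alone). Epidermal differentiation had 1 rise, of Ivl (1.33 ± 0.19), and 2 falls among 25 (the same adjusted over the list alone), of Klf4 and of Sprr3, a cornified envelope gene at least 2.33-fold lower and not well above background after miR-365a. Marveld2 (1.06 ± 0.12), F11r (0.86 ± 0.12) and the splicing regulator gene Esrp2 (0.89 ± 0.15) rose among 25 epithelial junction genes (5 rose and 1 fell adjusted over the list alone). Sel1l (2.30-fold) and Canx rose and 4 of 20 endoplasmic reticulum genes fell (2 and 7 adjusted over the list alone), led by Pdia6 (-1.08 ± 0.16), Creld2 (-1.17 ± 0.20) and the stress sensor gene Atf6 (-1.40 ± 0.25). Of 27 integrated stress response genes Chac1 (0.81 ± 0.13) and Sesn2 (0.94 ± 0.23) rose and Asns (-0.56 ± 0.12), Mthfd2 (-0.49 ± 0.11) and Atf4 fell (2 and 4 adjusted over the list alone). The cytoskeleton and migration list after miR-365a was called without NC replicate 3 (adjusted p = 0.00474) and without miR-365a replicate 2 (adjusted p = 0.00440), in a range of 0.00440 to 0.855. Without NC replicate 3 the invasion and matrix proteolysis list after miR-365a (range 0.00448 to 0.979) and the endoplasmic reticulum chaperones list after miR-365a (range 0.00448 to 0.855) were called as well, both with an adjusted p = 0.00448. The epithelial junction list after miR-365a was called without NC replicate 4 (adjusted p = 0.0366, range 0.0219 to 0.801). Among 15 genes of the microRNA machinery Prkra (1.05 ± 0.16) and Tnrc6a (0.77 ± 0.18) rose and Ago1 (-0.72 ± 0.14) and Tnrc6c (-1.19 ± 0.25) fell (the same adjusted over the list alone).

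A few lists held fewer calls. Krt8 rose among 9 keratins, Twist2 and Zeb2 among 19 mesenchymal transition genes, Pdgfrb among 6 fibroblast markers and Csf1r among 6 leukocyte markers, all of them also adjusted over the list alone. Of 25 mitochondrial respiration genes 1 rose (0 adjusted over the list alone). Zeb2 was at least 1.2-fold and Pdgfrb at least 2.06-fold higher, neither well above background in NC cells. Among 6 endothelial markers limma called 0 genes (2 at an unadjusted p under 0.05). The interferon response list had a median of 0.64 with 29 of 32 members above 0, but was not called (camera adjusted p = 0.143), and only Oas3 rose (1.81 ± 0.40), not adjusted over the list alone. Its levels differed as much between NC arrays: the mean-centred list median was -0.83 on NC replicate 1, 1.08 on replicate 2, -0.78 on replicate 3 and -0.11 on replicate 4. For the keratin, mesenchymal, NF-kB, TGF-beta, fibroblast and endothelial lists the median, mean and test differed in sign.

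Among genes above background on all 4 arrays of the set, listed after their values were seen, the imprinted gene Mest fell most (-3.39 ± 0.30, 10.5-fold, adjusted p = 0.00338). It was followed by Rell1 (-3.03 ± 0.18), the protein C receptor gene Procr (-2.81 ± 0.24, 7.02-fold), Smim13 (-2.79 ± 0.15), Ammecr1 (-2.68 ± 0.18), the chromatin protein gene Hmga2 (-2.60 ± 0.36), Oaz2, which restrains ornithine decarboxylase (-2.46 ± 0.18), Golm2, Sfmbt1 and Erp44. A second Oaz2 probe did not move (-0.0048). The largest rises were those of Ccl7 (2.55 ± 0.50, 5.87-fold), the microfibril gene Mfap5 (2.54 ± 0.25), the scramblase gene Xkr8 (2.37 ± 0.14), Txnip, which binds thioredoxin (2.25 ± 0.23), Armh3, Edn1, encoding endothelin 1 (2.15 ± 0.40), Frat2, Rab19 and Tfpi. On the NC arrays Mfap5 and Tfpi were lower in the 0.6 set than in the 0.2 set (log2 differences of -3.70 and -3.59). The rule fixed beforehand again led to dim probes. It picks genes by fitted change, not by bound. Cyp4b1 was at least 6.73-fold higher, Serpinb9g 5.66-fold, Asb4 4.26-fold, Tchhl1 3.78-fold, Serpinb9c 3.48-fold, Prg4 3.33-fold and Olfr875 3.18-fold. Each is a lower bound from the lower miR-365a array for a gene not well above background in NC cells. Outside the pick, Serpinb9f (at least 12.5-fold) and Htr1d (at least 6.37-fold) had larger bounds than Serpinb9g. A second Asb4 probe gave -1.24 and was not called. Serpinb9e, of the same serpin cluster, was well above background on only 1 of the 2 NC arrays and rose too (adjusted p = 0.00834). Among the picked falls Prom1 was at least 4.73-fold lower, Mup4 3.02-fold and Pttg1ip2 1.36-fold. Each is a lower bound from the lower NC array for a gene not well above background after miR-365a. Adra2c was well above background on only 1 of the 2 miR-365a arrays and fell too (adjusted p = 0.0458), with Mest, Rell1 and Procr completing the falls.

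In all, 2814 of 17855 genes were called after miR-365a, 1387 higher and 1427 lower, of which 396 and 681 by at least 2-fold. At an unadjusted p under 0.05 there were 5570. Of the 2814, 2675 were well above background on at least 1 array of each side, 98 dim in NC, 38 dim after miR-365a and 3 on neither side. Arrays of the groups did not overlap for 61.6% of genes, where chance gives 33.3%. All arrays of this comparison share slide 4. The genes called after miR-365a fell to 1057 without a filter on dim probes, to 640 without miR-365a replicate 1, to 588 without miR-365a replicate 2, to 731 without NC replicate 3 and to 1375 without NC replicate 4. They numbered 4411 with neighbouring arrays as a block, an alternative chosen after the data were seen that the labels do not pair, and 3749 with slide as a random block.

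**Figure D2:**
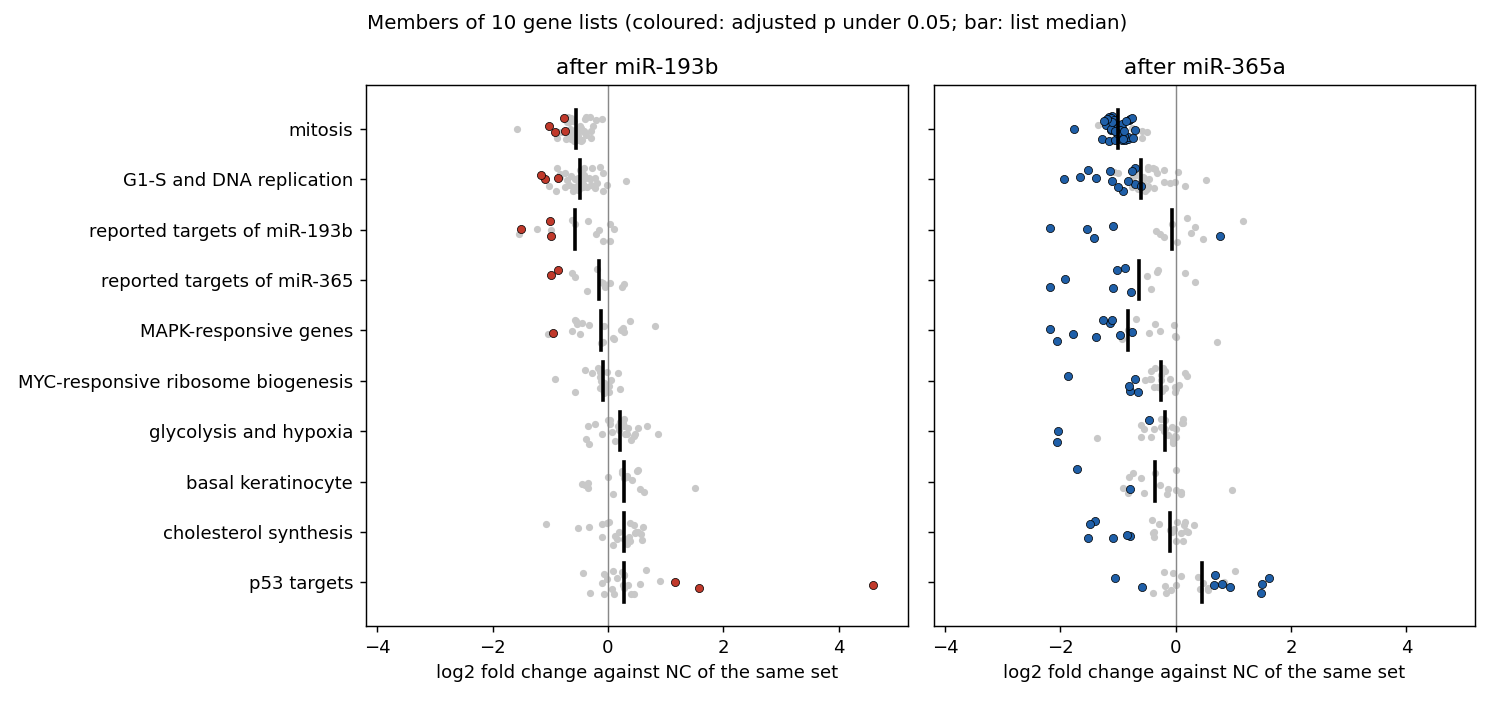
Log2 fold change against the NC arrays of the same set (horizontal axis) of each measured member of 10 gene lists after miR-193b (left) and miR-365a (right); coloured points have an adjusted p under 0.05 and bars are list medians. Mitosis medians are -0.56 and -0.997, MAPK-responsive medians -0.11 and -0.83.

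The third comparison asked how the effects of the 2 microRNAs relate, each against its own NC arrays. Across genes the effects correlated weakly (Pearson 0.226, Spearman 0.279, over 17855 genes, which are not independent replicates). Over the 15490 genes above background on at least 1 array of every group both were 0.307. Of the called genes, 120 rose after both, where independence gives 24.3 (odds ratio 7.98, Fisher's exact p = 4.74e-53). A further 53 fell after both, against 16.5 (odds ratio 4.10, Fisher's exact p = 1.05e-14). Genes with opposite calls numbered 20 and 14, against 25.0 and 16.0 (Fisher's exact p = 0.343 and 0.695). Both comparisons share each gene's variance estimate and the filter, which can raise the overlap in either direction. Genes are also not independent, so these expected counts and p values are not exact. Calls in the same direction (120 and 53) outnumbered opposite ones (20 and 14). Named after their values were seen, Fndc7, Fyco1, Sprr2i, Gdpd2 and Tmem53 rose after both, Fyco1 by 1.73 and 1.57 and Gdpd2 by 1.42 and 1.90 on the log2 scale. Lpcat1 (-1.54 and -1.30), Gprc5b, Camk2n2, the oligosaccharyltransferase gene Ostc, the deadenylase gene Cnot6, Fbxo5, which restrains the anaphase-promoting complex, and Ccna2 fell after both. Defb14 rose after miR-193b (1.94) and fell after miR-365a (-1.76), and Dennd6a did so as well (1.08 and -2.08). On the NC arrays Defb14 was already higher in the 0.6 set than in the 0.2 set (log2 difference of 6.36). Timp2 (-1.03 and 0.61), Spint1 (-1.21 and 0.67), Ankrd13a (-1.45 and 0.53) and Slc44a2 (-0.87 and 0.94) fell after miR-193b and rose after miR-365a.

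The difference between the effects itself was called for 623 genes, 195 higher and 428 lower after miR-365a relative to miR-193b (3595 at an unadjusted p under 0.05). Ccnd1 was among them (-1.62 ± 0.30, adjusted p = 0.0447), and for Max the adjusted p was 0.0502. By this test the difference was positive for Stmn1 (1.44 ± 0.15) and Rhoc (1.72 ± 0.31), which had fallen after miR-193b. For Nfib (-1.72 ± 0.19), Odc1 (-1.82 ± 0.26) and Cd44 (-1.80 ± 0.33) it was negative. Among bright genes named after their values were seen, the largest positive differences were those of Xkr8 (2.72 ± 0.19), Apln (2.56 ± 0.40), Iqcb1 (2.42 ± 0.44) and Kat2b (2.16 ± 0.27). Apln and Kat2b fell after miR-193b (-2.23 and -1.90) and were not called after miR-365a (0.33 and 0.26). The largest negative differences were those of Defb14 (-3.70 ± 0.48), Dennd6a (-3.17 ± 0.19), Mest (-3.08 ± 0.43) and Golm2 (-2.93 ± 0.30). Of 30 lists 5 were called, all lower after miR-365a relative to miR-193b. The median difference was -0.41 for mitosis (camera adjusted p = 1.66e-05) and -0.44 for glycolysis and hypoxia (4.14e-04). It was -0.44 for cholesterol synthesis (0.00134), -0.50 for basal keratinocyte (0.00256) and -0.49 for MAPK-responsive genes (0.0232). With an estimated correlation the adjusted p was 0.665 to 0.737. With fry it was 0.0410 for glycolysis and hypoxia, and the other 4 were not called (0.178 for mitosis and for cholesterol synthesis, 0.103 for basal keratinocyte and 0.0811 for MAPK-responsive genes). No mitotic gene was called in the difference (0 by limma), and 2 each were in the MAPK-responsive, basal and cholesterol lists and 1 in the glycolysis list, against 3, 3, 3 and 1 adjusted over the list alone. The microRNA and the array set cannot be told apart here, and the genes called between the effects of miR-365a and miR-193b numbered 0 without a filter on dim probes and 0 without NC replicate 4 (3491 and 3109 unadjusted). They numbered 284 without NC replicate 1, 112 without miR-193b replicate 1, 225 without miR-193b replicate 2, 12 without either miR-365a replicate and 42 without NC replicate 3, but 2590 without a set term and 1256 with neighbouring arrays as a block (chosen after the data were seen).

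**Figure D3:**
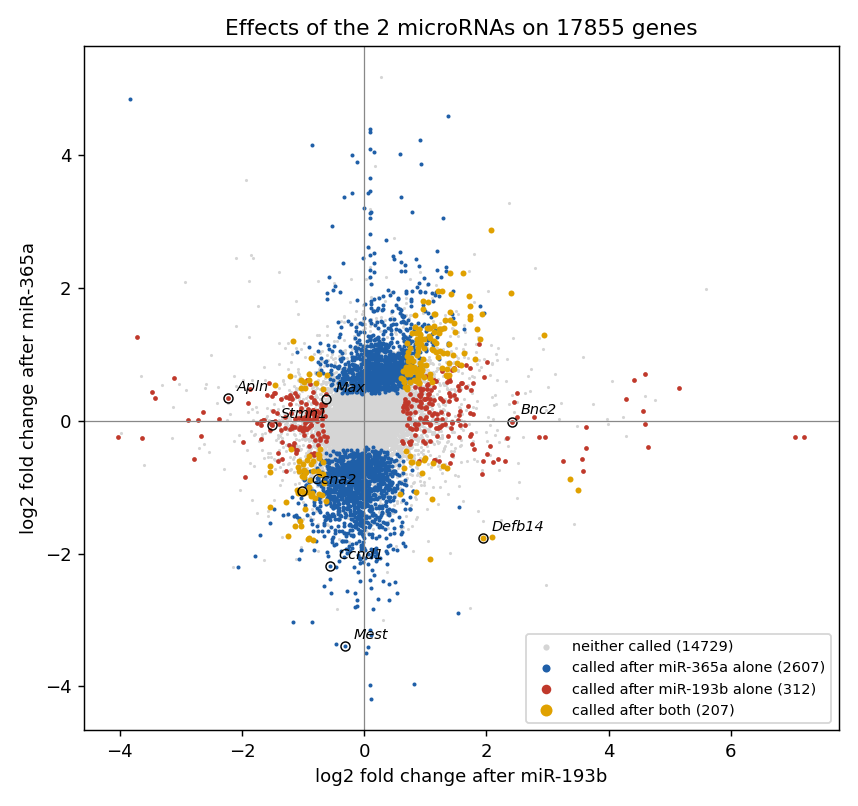
Log2 fold change after miR-193b (horizontal) against that after miR-365a (vertical) for 17855 genes (points), coloured by the comparison in which they were called. Of these, 2607 were called after miR-365a alone, 312 after miR-193b alone and 207 after both.

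The NC arrays differed between the sets. Defb14 was 82.3-fold higher in the 0.6 set (6.36 ± 0.34, SE, n = 2 and 2, adjusted p = 0.00112). The cornified envelope genes Cnfn (5.86 ± 0.69), Sprr1a (4.03 ± 0.27) and Sprr2d (3.85 ± 0.16), the protease inhibitor gene Stfa1 (4.55 ± 0.68) and the epidermal protease gene Asprv1 (3.70 ± 0.66) were higher there too. Lower in the 0.6 set were Pcolce2 (-4.17 ± 0.45), Mfap5 (-3.70 ± 0.25), Tfpi (-3.59 ± 0.41), the homeobox gene Hoxc6 (-2.69 ± 0.37) and the surface antigen gene Cd34 (-2.47 ± 0.23). All these were named after their values were seen. Of 25 epidermal differentiation genes 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 0.0263; adjusted p = 0.999 with an estimated correlation). Of the 10, Sprr3, Dsg1a, Klk5, Klk7 and Casp14 were not well above background on either NC array of the 0.2 set. Of 6 measured fibroblast markers 3 were higher, Fbln1 (1.09 ± 0.15) and, not well above background in the 0.2 set, Thy1 and Col1a2, and 0 lower (4 and 1 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.263). Of 6 endothelial markers 2 were higher, Kdr (1.57 ± 0.25) and Eng (1.18 ± 0.18), and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 0.164). Neither list was called. Other lists without a camera call held more called genes, where 15.5% of all genes tested were called. In glycolysis and hypoxia 6 of 25 were higher and 0 lower, with a median of 0.35 (camera adjusted p = 0.0603, and 0.0211 with fry). Among 25 epithelial junction genes 6 were higher and 2 lower, and among 19 mesenchymal transition genes 6 and 4. Mitosis genes had a median of -0.30, with 3 of 44 lower (0 adjusted over the list alone; camera adjusted p = 4.79e-08). Genes of G1-S and DNA replication had a median of -0.18 with 0 of 44 called by limma (camera adjusted p = 0.0250), and for both the adjusted p was 0.999 with an estimated correlation (0.185 for mitosis and 0.734 for G1-S with fry). In all 2772 genes were called, 2060 higher and 712 lower in the 0.6 set (6173 at an unadjusted p under 0.05). Amount label, slide and set coincide here, so this contrast describes the sets and answers no question about the microRNAs. The genes called between the NC arrays of the 2 sets numbered 1027 without a filter on dim probes and 1376 with slide as a random block. They numbered 1356 without NC replicate 1, 1273 without NC replicate 3, 485 without NC replicate 4 and 1736 without either miR-365a replicate.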

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

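The first test below was fixed before the data were examined, and results are given for lists and genes that exceeded its limit. It asked, for each list median and named gene, whether 1 of the 4 NC arrays lay far from the other 3, as the gap to the nearest array over the range. Of 192 groups of 4 values, 11 exceeded the limit. At 1 in 20 this would be 9.6 if the 4 arrays were 1 homogeneous group, but they come from 2 sets that differ in many genes. The number of flags is close to that rate and by itself sets no array apart. On NC replicate 4 the G1-S and DNA replication list had a median of -0.04 against 0.37 to 0.42 on the others (ratio 0.879). The p53 target list had 0.01 there against -0.26 to -0.23 (0.906), and the NF-kB and cytokine list 0.52 against -0.27 to -0.14 (0.835). The same array stood apart for Cd44 (3.72 against 2.99 to 3.06, ratio 0.894), Erp44 (-0.46, ratio 0.866) and the dim Pttg1ip2 (-3.12, ratio 0.934). NC replicate 2 did so for Asns (5.68, ratio 0.867) and Olfr875 (-6.04, ratio 0.833), and NC replicate 3 for Mlx (0.78, ratio 0.859). All arrays were kept, and leaving out each is described with the alternatives.

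The effects of the microRNAs differed, as miR-365a minus miR-193b, by a median of -0.49 for MAPK-responsive genes, -0.41 for mitosis, -0.50 for basal keratinocyte genes, -0.44 for cholesterol synthesis and -0.44 for glycolysis and hypoxia, and by -1.62 for Ccnd1. Each microRNA was measured in 1 array set only, so these differences belong to the microRNA and the set together. With an estimated correlation no list kept its call (adjusted p from 0.665 to 0.737), and 0 mitosis genes were called (13 at an unadjusted p under 0.05).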

How the results depend on the processing

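The neighbouring-array block and the filter to probes well above background on the 4 arrays of the own set were chosen after the data were seen; the other alternatives were fixed before. The genes called after miR-193b (519) numbered 975 with normexp background correction, 848 with the deposited log2 values, 11 without a filter on dim probes, 871 with probes above background on all 8 arrays, 812 with those above background on the 4 arrays of the own set, 171 with slide as a fixed term, 293 without a set term, 0 in the own set alone (3108 unadjusted), 1042 with a trended robust variance, 1368 with neighbouring arrays as a block, 287 at an adjusted p under 0.05 and 2-fold, 6 at an adjusted p under 0.01, 3806 unadjusted, and 29 to 281 without 1 array. Normexp moved their higher share from 60.3% to 70.6%. The genes called after miR-365a (2814) numbered 1057 without a filter, 4411 with neighbouring arrays as a block, 1077 with 2-fold, 677 at an adjusted p under 0.01, 5570 unadjusted and 588 to 2831 without 1 array. The genes called between the effects of miR-365a and miR-193b (623) numbered 1048 with normexp (median of all genes -0.13 against -0.02), 989 with the deposited log2 values, 0 without a filter (3491 unadjusted), 1061 above background on all 8 arrays, 1017 with slide as a random block, 133 with slide fixed, 2590 without a set term, 1128 with a trended robust variance, 1256 with neighbouring arrays as a block and 0 to 556 without 1 array. The genes called between the NC arrays of the 2 sets (2772) numbered 1027 without a filter, 1376 with slide as a random block and 485 to 2400 without 1 array; their higher share of 74.3% was 63.4% with normexp and 60.9% with the deposited log2 values. The correlation of the 2 effects across genes (0.226) was 0.282 with normexp, 0.303 with the deposited log2 values, 0.124 without a filter, 0.313 above background on all 8 arrays or on the 4 of the own set, 0.148 with slide fixed, 0.172 to 0.236 without 1 array, and reversed to -0.011 without a set term. Defb14 after miR-193b reversed to -1.24 without a set term, where miR-193b is compared with NC arrays of both sets. The cause of the other moves was not tested.

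Ccnd1 after miR-365a (adjusted p 4.52e-04 to 0.0286) was called under every alternative. Max after miR-193b ranged from 0.0238 to 0.229 and was called under 6 alternatives, and Stmn1 after miR-193b ranged from 0.00190 to 0.133. All list calls were lost with an estimated correlation. Other settings ended some, by adjusted p. The p53 targets list after miR-193b gave 0.0719 with normexp, 0.211 with slide fixed and 0.123 with fry. The reported targets of miR-365 list after miR-193b gave 0.211 with slide fixed and 0.137 without a set term. The G1-S and DNA replication list after miR-193b gave 0.104 with fry. The p53 targets list after miR-365a gave 0.0516 with slide fixed, 0.0518 in the own set, 0.0655 without a set term and 0.0621 with neighbouring arrays as a block. The basal keratinocyte list after miR-365a gave 0.0636 with slide as a random block, 0.131 with the mean over probes, 0.0816 with every probe and 0.0684 with fry. The cholesterol synthesis list after miR-365a gave 0.0644 with normexp, 0.0519 above background on all 8 arrays, 0.106 with the mean over probes, 0.0816 with every probe and 0.212 with fry. The glycolysis and hypoxia list after miR-365a gave 0.0636 with slide as a random block, 0.314 without a set term, 0.0537 with a trended robust variance and 0.0660 with every probe. Other settings added calls. With fry the MYC-MAX network list after miR-365a gave 0.0346, the CDK inhibitors and quiescence list after miR-365a 0.0430, the apoptosis list after miR-365a 0.0430, the reported targets of miR-193b list after miR-365a 0.0430 and the RAS-MAPK pathway list after miR-193b 0.0200. Without a filter on dim probes the MYC-MAX network list after miR-365a gave 0.0478, the CDK inhibitors and quiescence list after miR-365a 0.0240, the apoptosis list after miR-365a 0.0261 and the epithelial junction list after miR-365a 0.0219. In the own set alone the contrasts of effects and of NC sets have no value, nor has the NC contrast with slide fixed, without a set term or with neighbouring arrays as a block. That block pairs arrays of the same replicate order, which the labels do not pair; deviations of such neighbours correlated with r = 0.261 in the 0.2 set and 0.427 in the 0.6 set (0.433 and 0.599 over genes above background on all 8 arrays), and with 0.0072 and -0.094 across sets (-0.026 and -0.172). A fit without 1 array takes the lone array of a group to vary like the others. With slide as a fixed term the miR-193b effect likewise rests on slide 1, with 1 miR-193b and 1 NC array. Its spread is then that of the 0.6 set, and the difference between the effects shares this limit. Ratios of dim probes depend on the background subtracted, so only lower bounds are given for them. Alternatives for seed sites in 3′ untranslated regions, intended before the data were examined, were not run.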

Other observations

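Of the tests below, the search of probe sequences for seed sites was chosen after the files were seen but its predictions were written before its result, and both tests on the NC arrays and the interferon values were chosen after those results were seen.

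Genes whose 60-base probe holds a seed match of the transfected microRNA were lower. The p values given here are unadjusted. Over the 8 tests of this search, camera with the preset correlation gave an adjusted p of 3.82e-06 (miR-193b) and 1.02e-11 (miR-365a). Those with an estimated correlation were not adjusted. Adjusted in the same way over the 8 tests, the value after miR-193b would exceed 0.05. The value after miR-365a would lie only just under 0.05. After miR-193b, 93 genes with its site shifted by -0.14 against the rest (camera p = 9.54e-07, n = 93 genes; 0.0182 with an estimated correlation), and 10 fell and 0 rose, Stmn1, Zdhhc18 (-1.28) and Serinc2 (-1.05) among them. After miR-365a, 83 genes with its site shifted by -0.49 (camera p = 1.27e-12, n = 83 genes; 0.00609 with an estimated correlation), and 28 fell and 1 rose, with falls of Suclg2 (-2.16), Adm (-2.05), Vbp1 (-1.96) and Sc5d (-1.52). Sites of the other microRNA and reverse complements gave camera p from 0.129 to 0.974 (n = 71 to 93 genes), and 2267 to 9551 of 10000 random lists lay as low. For the sites of the transfected microRNA, 15 of 10000 random lists lay as low after miR-193b and 0 after miR-365a. This is consistent with direct repression of part of the genes that fell, although probes cover only 60 bases of each transcript and the Stmn1 probe also holds the reverse complement.

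The NC arrays of the sets differed, among others in Defb14, Cnfn, Sprr1a and Hoxc6, genes chosen after their values were seen. By number of calls, background of dim probes may not be the main source, because 12.6% of 14613 genes well above background on all 8 arrays were called. The other genes were called more often (28.7% of 3242), with 804 higher and 128 lower against 1256 and 584 among the bright genes. Most calls of at least 4-fold were among these other genes (259 against 101), so for large differences background stays open. On the NC arrays of the 0.6 set 5 of 13 fibroblast markers were well above background, Col1a2, Col6a1, Pdgfra, Thy1 and Fbln1. The abundant Col1a1, Col3a1, Dcn and Lum were not. This makes fibroblast RNA in the 0.6 set an unlikely source of most of the genes higher there, by a limit set after the result was seen. It does not exclude a small share of RNA of other cells in the 0.6 set. There 3 of 6 measured fibroblast markers and 2 of 6 endothelial markers were higher and 0 lower (medians of 0.88 and 0.86). Fibroblast RNA in the 0.2 set, where Pcolce2, Mfap5 and Cd34 were higher, was not tested. The source remains open, no biological explanation was tested, and the amount label, slide and set coincide.

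Interferon-responsive genes varied between arrays given the same microRNA. Over 24 members well above background on all 8 arrays, NC replicate 2 exceeded NC replicate 1 in 24, by a median of 1.81 and by 5.12 for Oas1a, and miR-193b replicate 2 exceeded replicate 1 in 23 (median 0.74). NC replicate 4 exceeded replicate 3 in 21 (0.53), and miR-365a replicate 2 exceeded replicate 1 in 18 (0.24). Both miR-365a arrays (list medians of 0.13 and 0.39) lay above both NC arrays of their set (-0.78 and -0.11), and the difference of 0.64 over 32 genes was not called. It is close in size to the gap between the NC arrays of its own set and smaller than that in the other set.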
